A study of Homo sapiens with 48 samples.

How the data were processed

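The deposited files used here were 48 files of read counts per gene, each from a single library, and the authors' lists of differentially expressed genes. Per the submitters' processing notes, libraries were made from Trizol-extracted RNA with the Kapa stranded mRNA kit, base calls came from CASAVA 1.8.2, reads were aligned to GRCh38 with STAR 2.4.0i, and reads per gene were counted with HTSeq 0.6.1. The same notes state that alignments were run again with updated software for the updated lists. The strand setting and the annotation release of the counting step were not stated in the sources used here. The values per gene are counts, as made by the authors and as the labels describe them, with no normalization. The authors' lists of changed genes hold log2 fold changes and adjusted p-values made by the authors, with a test that the deposited files do not name. A further file with 48 columns of counts over protein-coding genes was not used, because no label ties its column codes to the libraries.

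The counts covered 64253 Ensembl gene identifiers, of which 56591 were matched to GENCODE release 29 for symbols and GRCh38 positions. The 513 genes of chromosome Y with XIST and TSIX were removed before every test. Over the 48 libraries the median share of reads outside any gene was 9.06%, and the median share of reads that fell in more than 1 gene and were left uncounted was 2.25%. Genes with near-identical copies, such as HBA1 and HBA2, the metallothioneins or HSPA1A and HSPA1B, lose reads to that rule and to multiple alignment, so their levels are less certain.

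Counts were scaled with the trimmed mean of M values (TMM) and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3). Genes were kept by filterByExpr, with a minimum count of 10 in the smallest group and a minimum total of 15, which left 15766 genes. A single model over all 48 libraries held 1 term per subject (16 subjects) and separate time effects in each arm, so each change is a change within subjects. The difference between arms was the contrast of their time effects, that is, the blockade change minus the control change. The comparison of the arms before exercise used the 16 pre-exercise libraries without subject terms and tested 14180 genes. Benjamini-Hochberg adjustment was applied over all genes tested in a comparison, and the threshold was an adjusted p under 0.05. Log2 changes of genes are given with a standard error, taken as the absolute log2 change divided by the square root of the test's F statistic. It is derived from the same test as the p-value and is not a separate measure of spread. Levels are given as counts scaled to a common library size (CPM) with the SD over 8 libraries.

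Subjects were told apart by arm and replicate number. Some numbers occur in both arms, and the labels do not say whether they stand for the same people, so they were treated as different subjects, as the series describes 8 subjects in each arm. A check on the tested genes compared libraries after the arm and time means were removed: the correlation was above 0.1 in 48 of 48 pairs of libraries from 1 subject, with a mean of 0.545, against a mean of -0.075 between subjects. No pair of replicate libraries was close enough to be the same counts entered again, since the lowest chi-square per degree of freedom among them was 29.6.

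A response score measured the size of the exercise response in each subject. It is the mean, over responding genes, of the change in log2 CPM from before exercise (prior count 2), signed so that a change in the usual direction is positive. Responding genes were chosen from a fit with time effects common to both arms, at an adjusted p under 0.05 and an absolute log2 change of at least 1, so that the choice did not use the arms. Arms were compared with an exact two-sided permutation test over all 12870 labellings of 8 against 8 subjects.

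The 29 gene lists cover exercise responses and cell type markers. Each was tested against all other genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. Lists with at least 3 measured members were tested, which gave 28 lists, or 26 before exercise. Counts of members are given over all genes tested and adjusted over the list alone. The tests, the lists, the rule for naming genes and most alternative settings were set before the data were examined.

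Genes were named by this rule. Within an arm, the 10 largest rises and the 10 largest falls were taken among genes with an adjusted p under 0.05, a symbol, a mean log2 CPM of at least 1 and the same direction in at least 7 of 8 subjects. From each list up to 4 members with the lowest adjusted p were added. PPARGC1A, PDK4, VEGFA, IL6, FOS, NR4A3, CCL2, HDC, HNMT, HRH1 and HRH2 were always taken where tested. HRH2 was not tested, because its counts did not pass the expression filter.

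As a self-test, 200 genes were changed by known folds in simulated counts with a spread between subjects of 0.4 (SD, log2). The test of control 3 h against before recovered 65.7% of 1.5-fold, 85.1% of 2-fold and 97.0% of 4-fold changes, with 5.71% false calls among those made. For the difference between arms at 3 h it recovered 47.8%, 58.2% and 93.9%, with 5.67% false calls. Before exercise it recovered 8.96%, 52.2% and 86.4%, with 6.67% false calls. The simulated folds were the same in every subject, and each gene had a single dispersion at all time points. In the real libraries the variance within groups at 3 h was a median of 1.48 times that before exercise over all genes. These rates may therefore not hold for genes whose response varies between subjects. Other tools run were DESeq2 1.42.0 and limma-voom. Files were read with data.table, version 1.17.8, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.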

Results

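RNA sequencing was carried out on biopsies of the vastus lateralis, a thigh muscle, taken from 16 subjects before exercise, immediately after it and 3 h after it. In the control arm 8 subjects exercised without blockade, and in the blockade arm 8 subjects took drugs against the H1 and H2 histamine receptors before exercise. This gave 48 libraries in 6 groups of 8. The series asks how much of the muscle's transcriptional response to exercise depends on those receptors. The labels do not say whether the pre-exercise biopsy came before the drugs were taken.

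Each library held between 15.9 and 37.7 M (1e+06) reads counted in genes, with a median of 28.6 M. The range was 23.6 to 35.1 M before exercise, 23.0 to 37.7 M immediately after and 15.9 to 35.1 M at 3 h in the control arm. In the blockade arm the ranges were 22.8 to 32.9, 21.2 to 33.5 and 22.4 to 33.4 M. A median of 23122 genes had at least 1 read. Mitochondrially encoded genes took a median of 23.2% of the reads. In 1 control 3 h library they took 73.6%, where the next highest control 3 h library had 25.6%, and that library had 17451 detected genes. It is kept in the values here unless a value is said to be without it, an alternative chosen after the data were seen.

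**Figure D1:**
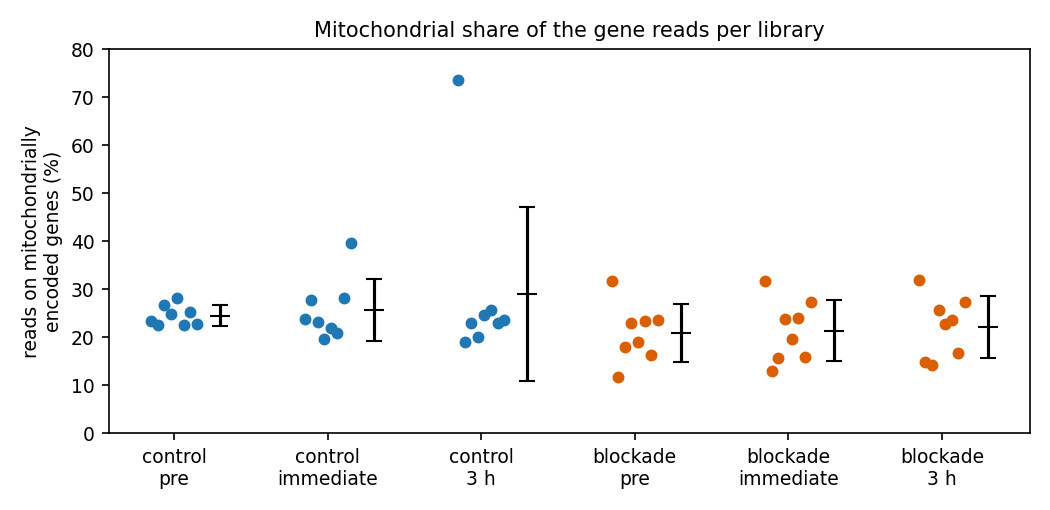
Share of reads from mitochondrially encoded genes (y axis, percent of counted reads) in each of the 48 libraries, by arm and time, with group means and SD. In 1 control 3 h library the share was 73.6%, and the 24 blockade libraries stayed between 11.8% and 32%.

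The first comparison asks what control muscle did straight after exercise. Genes of the immediate early response, which code for transcription factors and signalling proteins induced within minutes, rose most. NR4A2, an orphan nuclear receptor, rose by 4.86 ± 0.54 (log2, SE, n = 8), and EGR3, a zinc finger transcription factor, by 5.28 ± 0.81, both in 8 of 8 subjects. CYR61, a matrix protein that stimulates vessel growth, rose from 4.58 ± 2.47 to 93.8 ± 27.5 CPM. CX3CL1, a chemokine shed by endothelium, rose 11.6-fold (log2 3.53 ± 0.33, adjusted p = 9.01e-09, in 8 of 8 subjects). Falls were smaller and included GIMAP7, a GTPase of lymphocytes and endothelium, at -1.56 ± 0.19, and DEPP1, a FOXO-regulated autophagy gene, at -1.50 ± 0.29, in all 8 subjects each.

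Of the 27 immediate early genes measured in control muscle, 21 rose immediately after exercise, and 24 when adjusted over the list alone. The list had a median log2 change of 2.53 (camera adjusted p = 1.23e-31, and adjusted p = 0.026 with an estimated correlation, or 0.0710 without the control 3 h library of high mitochondrial share). Examples beside those above were NR4A1 at 3.12 ± 0.31 and FOS, a subunit of the AP-1 factor, at 4.57 ± 1.18. The heat shock and unfolded protein list had 7 of 19 members up (10 adjusted over the list alone), among them the chaperone genes DNAJA1 at 1.03 ± 0.13, HSPH1 at 0.70 ± 0.12 and the collagen chaperone SERPINH1 at 1.12 ± 0.18. Its camera adjusted p was 6.56e-10, and the adjusted p = 0.111 with an estimated correlation. Myogenic and atrophy genes had 4 of 22 members up (6 adjusted over the list alone), including FOXO1, a transcription factor of muscle wasting and fasting, at 0.96 ± 0.23 and the myogenic factor MYOD1 at 0.68 ± 0.19. That list gave an adjusted p of 0.00579, and adjusted p = 0.0437 with an estimated correlation, or 0.0710 without that control 3 h library.

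Cytokine and inflammation genes in control muscle had 5 of 22 members up (10 adjusted over the list alone), with the neutrophil attractant CXCL2 at 3.19 ± 0.79 and the monocyte attractant CCL2 at 2.58 ± 0.74. The list reached an adjusted p of 2.88e-04, and adjusted p = 0.672 with an estimated correlation. Smooth muscle and pericyte markers had 4 of 8 members up (4 up and 1 down adjusted over the list alone), among them CNN1 at 2.58 ± 0.45, a calponin of contractile smooth muscle, and MCAM at 1.05 ± 0.19 (list adjusted p = 0.00595, and adjusted p = 0.14 with an estimated correlation). The vascular list had 4 of 25 members up, including VEGFA, the main vessel growth factor, at 0.75 ± 0.20, and THBS1, an inhibitor of vessel growth, at 3.31 ± 0.60 (list adjusted p = 0.206). Neutrophil markers had 0 of 8 members past the threshold, with a median of 0.30. The list of glucocorticoid-responsive genes had 1 of 12 members up, FKBP5 at 1.15 ± 0.25, and an adjusted p of 4.72e-04, with adjusted p = 0.14 with an estimated correlation. Nuclear respiratory chain genes and slow fibre genes passed downwards, with medians of -0.11 and -0.25 and 0 members past the threshold on their own (list adjusted p = 8.77e-04 and 0.00482, and adjusted p = 0.672 each with an estimated correlation).

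In all, edgeR called 759 of 15766 genes in control muscle immediately after exercise, 527 up and 232 down, of which 201 and 43 changed at least 2-fold. The count was 321 with library totals as the only scaling, 284 without the subject terms and 1563 when only the 16 libraries compared were fitted. With limma-voom and sample quality weights, chosen after the data were seen, it was 1754.

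The second comparison asks the same of muscle under blockade. NR4A2 rose by 4.36 ± 0.52 and KLF4, a zinc finger factor of endothelium and smooth muscle, by 2.70 ± 0.28, both in 8 of 8 blockade subjects. CX3CL1 rose 8.23-fold, to 41.2 ± 18.9 CPM (adjusted p = 1.54e-07). APOLD1, an early response gene of endothelium, rose by 2.95 ± 0.40 and SLC2A3, a high-affinity glucose transporter, by 2.38 ± 0.46. GIMAP7 fell by 1.21 ± 0.18 and AVPR1A, a vasopressin receptor, fell by 1.05 ± 0.19, each in 8 of 8 subjects.

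Of the immediate early genes, 14 of 27 rose in blockade muscle, and 24 when adjusted over the list alone, with a median of 2.05 (camera adjusted p = 5.81e-27, and adjusted p = 0.118 with an estimated correlation). FOS had a change of 2.66 ± 1.13 (adjusted p = 0.262) and was higher in 6 of 8 subjects. The heat shock list again had 7 of 19 members up (8 adjusted over the list alone), with DNAJA1 at 0.94 ± 0.13 (list adjusted p = 1.17e-09, and adjusted p = 0.182 with an estimated correlation). Smooth muscle and pericyte markers had 4 of 8 up, with ACTA2, smooth muscle actin, at 1.59 ± 0.29 (list adjusted p = 6.69e-04, and adjusted p = 0.133 with an estimated correlation). The vascular list had 3 of 25 up (4 adjusted over the list alone), among them VEGFA at 0.86 ± 0.20 and EDN1, the precursor of the constrictor peptide endothelin, at 1.75 ± 0.35. Its adjusted p was 1.6e-04, and adjusted p = 0.241 with an estimated correlation.

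In the cytokine list 1 of 22 members rose in blockade muscle (6 adjusted over the list alone), IL4R, an interleukin receptor, to 4.05 ± 1.09 CPM (list adjusted p = 0.00263, and adjusted p = 0.657 with an estimated correlation). Neutrophil markers had 0 of 8 past the threshold and a median of 0.87 (list adjusted p = 0.146). In the set tests the glucocorticoid-responsive, oxidative and nuclear respiratory chain lists also passed upwards and the fast fibre and fibroblast lists downwards, with adjusted p from 0.00263 to 0.018. With an estimated correlation their adjusted p lay between 0.274 and 0.657, and 1 member of these lists passed on its own (2 adjusted over the list alone), DDIT4, an inhibitor of mTORC1 growth signalling, at 1.24 ± 0.27.

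The test called 498 genes in blockade muscle immediately after exercise, 414 up and 84 down, of which 173 and 23 changed at least 2-fold. The count was 216 without the subject terms, 851 with only the libraries compared and 1145 with limma-voom and quality weights. The 2 arms shared 307 rising genes, where 13.8 are given by chance, and 44 falling genes against 1.24, and 0 genes went in opposite directions.

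The third comparison asks how control muscle had changed 3 h after exercise. PPARGC1A, the coactivator that drives mitochondrial gene expression, rose from 76.7 ± 10.8 to 914 ± 323 CPM, a log2 change of 3.52 ± 0.29 (adjusted p = 2.92e-10). NR4A3, an orphan nuclear receptor induced by exercise, rose 159-fold, by 7.31 ± 0.52. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 4.95 ± 0.34, and PDK4, the kinase that blocks entry of pyruvate into oxidation, by 2.99 ± 0.53. HRH1, the gene of the H1 receptor itself, rose from 0.508 ± 0.183 to 2.07 ± 1.36 CPM (log2 1.93 ± 0.28, adjusted p = 3.69e-06). HIF3A, a negative regulator of the hypoxia response, fell by 2.22 ± 0.25, and MSTN, which codes for the growth inhibitor myostatin, fell by 1.59 ± 0.21. All of these held in 8 of 8 subjects. On GRCh38, PPARGC1A (ENSG00000109819) spans positions 23755041 to 23904089 of chromosome 4, NR4A3 (ENSG00000119508) 99821855 to 99866891 of chromosome 9, and HRH1 (ENSG00000196639) 11137093 to 11263557 of chromosome 3.

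Cytokine and inflammation genes formed the list with the largest median change in control muscle at 3 h, 4.41, with 20 of 22 members up (21 adjusted over the list alone). CCL2 rose from 0.881 ± 0.366 to 61.6 ± 51.2 CPM, and SOCS3, the feedback inhibitor of cytokine signalling, by 6.29 ± 0.69. IL6, a cytokine that working muscle releases, was near the detection limit before exercise, at 0.0475 CPM, and reached 10.4 ± 9.53 CPM. The neutrophil markers rose with them: 8 of 8 passed, with a median of 2.67, and S100A9, a calcium-binding protein of neutrophils, went from 0.822 ± 1.14 to 5.54 ± 4.79 CPM. Camera gave an adjusted p of 3.34e-17 for the cytokines and 1.24e-05 for the neutrophil markers, with adjusted p = 0.0617 and 0.13 with an estimated correlation.

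Immediate early genes stayed high in control muscle, with 23 of 27 up at 3 h (23 adjusted over the list alone) and a median of 3.39. FOS rose from 2.18 ± 1.43 to 279 ± 346 CPM, and EGR1, a growth-response transcription factor, by 7.16 ± 1.05. The list's adjusted p was 2.67e-15, with adjusted p = 0.0863 with an estimated correlation. In the vascular list 16 of 25 rose (16 up and 1 down adjusted over the list alone), with VEGFA at 1.67 ± 0.21, its receptor KDR at 1.49 ± 0.16 and the hypoxia factor HIF1A at 1.51 ± 0.21. Oxidative and lipid regulators had 12 of 23 up and 1 down, over all genes and adjusted over the list alone, among them HK2, the muscle hexokinase, at 2.22 ± 0.26. These lists gave adjusted p of 2.92e-08 and 1.24e-05, and both had adjusted p = 0.0617 with an estimated correlation.

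Heat shock genes had 13 of 19 up in control muscle at 3 h, with HSPA5, the chaperone of the endoplasmic reticulum, at 0.53 ± 0.06 (list adjusted p = 8.23e-07, and adjusted p = 0.137 with an estimated correlation). All 5 measured metallothioneins, whose close copies share reads that were left uncounted, rose, with MT2A at 1.98 ± 0.36 (list adjusted p = 1.96e-04, and adjusted p = 0.117 with an estimated correlation). Among the 15 antioxidant genes 5 rose and 1 fell, and HMOX1, heme oxygenase, rose by 2.91 ± 0.29 (list adjusted p = 0.0331, and adjusted p = 0.343 with an estimated correlation). Myogenic and atrophy genes had 9 of 22 up and 4 down, with the stress gene GADD45A at 4.02 ± 0.45 and the insulin receptor substrate IRS2 at 2.27 ± 0.24 (list adjusted p = 0.024, and adjusted p = 0.0863 with an estimated correlation). Adjusted over the list alone, the counts of these 4 lists were the same. Of the 5 histamine pathway genes measured (list adjusted p = 0.25), HRH1 and SLC22A3, an organic cation transporter that carries histamine, rose (3 up and 1 down adjusted over the list alone), the latter by 0.75 ± 0.20. HNMT, which inactivates histamine by methylation, fell by 0.67 ± 0.18, and HDC, which makes histamine, had 0.88 ± 0.37 (adjusted p = 0.0745, higher in 6 of 8 subjects).

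Matrix genes had 4 of 21 up and 1 down in control muscle at 3 h, with a median of -0.11 and a mean of 0.28, and TNC, a matrix protein of repair, rose by 3.48 ± 0.48 (list adjusted p = 0.824).

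The count at 3 h in control muscle was 4557 genes, 2375 up and 2182 down, of which 773 and 205 changed at least 2-fold. It was 2368 without the subject terms and 2263 with only the libraries compared. Scaling by library totals moved the median of all genes from -0.05 to -0.27 in this comparison, and 33.1% of the calls were then rises, against 52.1%. Without the library of high mitochondrial share, an alternative chosen after the data were seen, 5005 genes were called.

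The fourth comparison asks what muscle under blockade had done by 3 h. PPARGC1A rose by 3.25 ± 0.29, to 820 ± 579 CPM, and NR4A3 by 6.53 ± 0.52, or 92.6-fold. ANGPTL4 rose by 4.26 ± 0.34 and PRKAG2, a regulatory subunit of the energy sensor AMPK, by 3.72 ± 0.38. VEGFA rose 3.17-fold (log2 1.67 ± 0.21, adjusted p = 1.18e-06). HIF3A fell by 1.86 ± 0.24, and the clock gene PER1 fell by 1.74 ± 0.21. All of these held in 8 of 8 blockade subjects.

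Among oxidative and lipid regulators 17 of 23 rose and 0 fell under blockade (17 adjusted over the list alone). ACSL1, which activates fatty acids, rose by 0.82 ± 0.11, and FABP3, which carries them in the muscle fibre, by 0.74 ± 0.11. The list's adjusted p was 1.78e-15, and 2.14e-04 with an estimated correlation, and it was the 1 list among the 13 past camera in this comparison that stayed past 0.05. The vascular list had 11 of 25 up (16 adjusted over the list alone), with KDR at 1.53 ± 0.16 and the angiopoietin receptor TEK at 1.28 ± 0.15 (list adjusted p = 1.15e-07, and adjusted p = 0.0503 with an estimated correlation). Slow fibre genes had 1 of 9 up (2 adjusted over the list alone) and fast fibre genes 2 of 10 down (3 adjusted over the list alone), namely ACTN3, the actin crosslinker of fast fibres, and MYLPF, a fast myosin light chain. Those lists gave adjusted p of 0.00258 and 0.00438, each with adjusted p = 0.379 with an estimated correlation.

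Cytokine genes had 16 of 22 up in blockade muscle at 3 h (17 up and 1 down adjusted over the list alone) and a median of 2.17. CCL2 rose by 3.06 ± 0.73, SOCS3 by 4.28 ± 0.68 and IL6 from 0.0602 to 1.45 ± 2.05 CPM. Neutrophil markers had 3 of 8 up (5 adjusted over the list alone), with S100A9 going from 0.220 ± 0.126 to 1.14 ± 0.974 CPM. Immediate early genes had 9 of 27 up (10 adjusted over the list alone) and a median of 1.03, with MYC at 2.88 ± 0.57, while FOS had 1.94 ± 1.15 (adjusted p = 0.297, higher in 5 of 8 subjects). The adjusted p were 2.58e-09, 0.00819 and 6.48e-06 in this order, and adjusted p = 0.258, 0.379 and 0.379 with an estimated correlation.

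In the matrix list 7 of 21 fell and 2 rose in blockade muscle at 3 h (11 down and 2 up adjusted over the list alone; list adjusted p = 0.379 with an estimated correlation), with the fibrillar collagen genes COL1A2 at -0.74 ± 0.21, COL3A1 at -0.76 ± 0.23 and COL5A1 at -0.69 ± 0.15, while the basement membrane collagen COL4A1 rose by 0.69 ± 0.16. Among fibroblast markers 4 of 8 fell, and all 8 when adjusted over the list alone, including PDGFRA at -0.61 ± 0.20 (list adjusted p = 0.258 with an estimated correlation). Metallothioneins had 3 of 5 up, the heat shock list 5 of 19, the antioxidant list 3 of 15 (4 adjusted over the list alone) and the nuclear respiratory chain list 1 of 25 (0 adjusted over the list alone). The 6 lists passed camera with adjusted p from 2.49e-04 to 0.0338, and had adjusted p from 0.258 to 0.379 with an estimated correlation. HRH1 had 0.54 ± 0.29 (adjusted p = 0.229, higher in 6 of 8 subjects) and HNMT fell by 0.64 ± 0.18.

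The count at 3 h in blockade muscle was 2237 genes, 1264 up and 973 down, of which 345 and 107 changed at least 2-fold. It was 864 with library totals, 641 without the subject terms, 3403 with limma-voom and quality weights, and 1459 without blockade replicate G. The arms shared 990 rising and 684 falling genes, where chance gives 190 and 135, and 4 genes went in opposite directions.

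**Figure D2:**
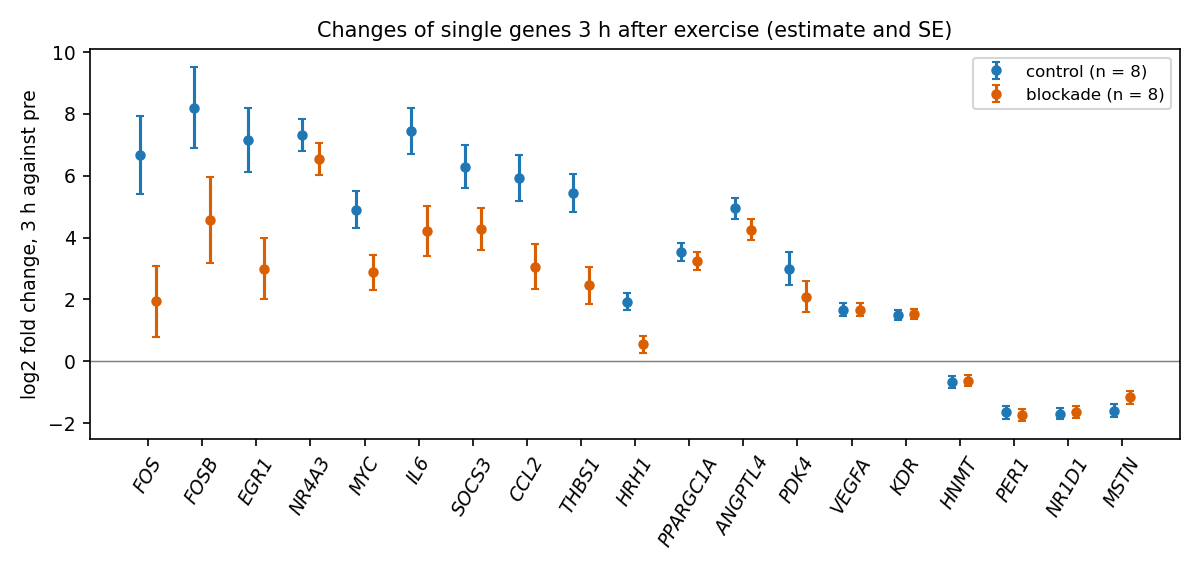
Change in log2 CPM from before exercise to 3 h after it (y axis) for 19 genes (x axis) in the control and blockade arms, as the model's log2 change with its standard error, n = 8 subjects per arm. PPARGC1A and VEGFA had close values in both arms, at 3.52 and 3.25 and at 1.67 and 1.67, while FOS had 6.68 and 1.94, and IL6 was near the detection limit before exercise.

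The fifth comparison is the series' main question, whether blockade changed the response, and it begins with the 3 h biopsy. FOS reached 279 ± 346 CPM in control and 42.5 ± 61.3 CPM in blockade muscle, and the blockade change minus the control change was -4.74 ± 1.65 (log2, SE, 8 against 8 subjects, adjusted p = 0.224). CYR61 had a difference of -3.12 ± 0.82 (adjusted p = 0.161), THBS1 -2.99 ± 0.85 (adjusted p = 0.164) and CCL2 -2.87 ± 1.04 (adjusted p = 0.233). For HRH1 it was -1.38 ± 0.41 (adjusted p = 0.171). Before exercise the estimates of FOS and CYR61 were higher in the blockade arm, by 1.17 ± 0.47 and 1.05 ± 0.40 (adjusted p = 0.781 each), which is part of their differences between changes. PPARGC1A had a difference of -0.28 ± 0.38 (adjusted p = 0.835) and VEGFA of 0.00 ± 0.29 (adjusted p = 1). No single gene passed the threshold, so these are differences in estimate. On GRCh38, FOS (ENSG00000170345) spans positions 75278774 to 75282230 of chromosome 14, CYR61 (ENSG00000142871) 85580761 to 85583962 of chromosome 1, CCL2 (ENSG00000108691) 34255218 to 34257203 of chromosome 17 and VEGFA (ENSG00000112715) 43770184 to 43786487 of chromosome 6.

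The immediate early genes had lower estimates of the change under blockade in 27 of 27 members at 3 h, with a median difference of -1.82. Of these, 19 passed when adjusted over the list alone. Of the 22 cytokine genes all 22 had lower estimates, with a median of -1.38 and 10 past the threshold adjusted over the list alone, among them OSMR, a receptor subunit for oncostatin M, at -0.91 ± 0.27, and ICAM1, an endothelial adhesion molecule, at -2.22 ± 0.76. Heat shock genes had 6 of 19 lower adjusted over the list alone, including DNAJA1 at -0.54 ± 0.18, with a median of -0.25. Before exercise the medians of these lists, blockade against control, were 0.33, 0.05 and 0.21 in that order. That is part of these differences between changes, and for heat shock genes it is close to the median difference in size. For the differences camera gave adjusted p of 4.07e-12, 6.4e-10 and 5.7e-05, and each list had adjusted p = 0.412 with an estimated correlation. Markers of leukocytes went the same way, with medians of -0.58 for neutrophils, -0.47 for monocytes and macrophages and -0.62 for T and NK cells, and adjusted p of 0.0254, 0.00724 and 0.0391 (adjusted p = 0.518, 0.412 and 0.412 with an estimated correlation).

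Changes by 3 h were also lower under blockade in the matrix, ribosomal, vascular and glucocorticoid-responsive lists, with median differences from -0.37 to -0.11. Ribosomal genes had stood higher in the blockade arm before exercise, with a median of 0.20. Their lower change is therefore not a lower level at 3 h. Changes of nuclear respiratory chain genes, slow fibre genes and oxidative regulators were higher, with medians of 0.19, 0.34 and 0.21. Before exercise the medians of these lists stood at -0.06, -0.16 and -0.12, blockade against control. NDUFS1, a core subunit of complex I, had a difference of 0.31 ± 0.09 (adjusted p = 0.161). For the oxidative regulators the mean, 0.04, lay far below the median. Camera adjusted p for these 7 lists ran from 1.58e-06 to 0.0452, and from 0.412 to 0.551 with an estimated correlation. In all 13 of 28 lists passed with the preset correlation, and 9 without the control library of high mitochondrial share.

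edgeR called 0 of 15766 genes for the difference at 3 h, with 1934 at an unadjusted p under 0.05 where 788 are given by chance. Under a threshold of 0.1 it called TUBA1C, a tubulin gene named after its values were seen, at -1.63 ± 0.30 (adjusted p = 0.0748), which went from 3.32 to 10.1 CPM in control and from 7.65 to 6.68 CPM in blockade muscle. Its higher level in blockade muscle before exercise is part of this difference between changes. limma-voom called 0 genes (1917 unadjusted), DESeq2 133 (49 up and 84 down), and edgeR 322 (36 up and 286 down) without an expression filter. FOS, CYR61, THBS1 and CCL2 were lower and past the threshold in both of the latter, NDUFS1 was higher in DESeq2 and HRH1 lower without a filter. The arms compared directly at 3 h, without subject terms, gave 311 genes, 21 higher and 290 lower under blockade, among them CYR61, OSMR, ICAM1, IL6 and HRH1, an alternative chosen after the data were seen. Leaving out 1 subject gave 12 genes without control replicate H, 2 without control replicate C, 1 without blockade replicate F and 0 without each of the other 13.

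The response score summarised the same question in 1 value per subject. Over 595 responding genes the 3 h score was 1.86 ± 0.456 (SD, n = 8) in control and 1.21 ± 0.606 in blockade subjects, a difference of -0.648 with an exact permutation p of 0.0305. The mean response under blockade was 65.2% of the control mean, and 493 of the 595 genes had the smaller mean change under blockade. Immediately after exercise 159 of 242 responding genes did too, although the score there gave an exact permutation p of 0.473. Individual scores overlapped, from 1.29 to 2.65 in control and from 0.235 to 2.14 in blockade muscle. With library totals the difference was -0.537 (exact p = 0.0690) and over falling genes alone -0.279 (exact p = 0.0617). Over the 16 versions that left out 1 subject the exact p ran from 0.00886 to 0.0645, and it was above 0.05 without control replicates D, F or G (0.0559, 0.0645 and 0.0517) or blockade replicates A or C (0.0603 and 0.0587).

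**Figure D3:**
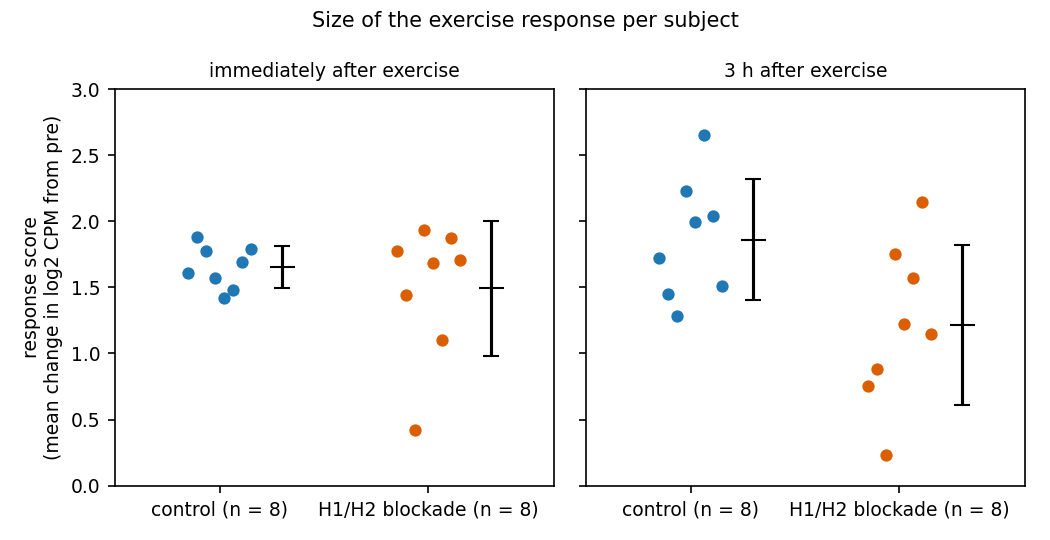
Response score (y axis, mean signed change in log2 CPM over the responding genes) of each subject immediately after and 3 h after exercise, by arm, with mean and SD, n = 8 per arm. At 3 h the means were 1.86 in control and 1.21 in blockade subjects, and the subjects of both arms overlapped.

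Immediately after exercise CYR61 had a difference between the changes of -1.42 ± 0.78, with levels of 4.58 and 9.39 CPM before exercise and 93.8 and 67.5 CPM after it in control and blockade muscle, and CTGF, a matrix growth factor gene, -0.96 ± 0.47, while ACSL1 had 0.43 ± 0.15 and CYCS, cytochrome c, 0.29 ± 0.09 (adjusted p = 1 for each of the 4). Nuclear respiratory chain genes had higher estimates of the change under blockade in 25 of 25 members, with a median of 0.17. So did slow fibre genes in 9 of 9, with a median of 0.36, and endothelial markers in 10 of 10, with a median of 0.28. Fast fibre genes had a median of -0.18 and immediate early genes of -0.50. The camera adjusted p were 1.23e-11, 6.24e-08, 8.22e-06, 2.35e-05 and 0.0133 in that order. Before exercise the medians, blockade against control, had the opposite sign, at -0.06, -0.16, -0.21, 0.16 and 0.33 in the same order. That is part of these differences between changes. The changes of the oxidative and vascular lists were higher too (camera adjusted p = 0.00843 and 0.031), with medians of -0.12 and -0.19 before exercise. The 7 lists had adjusted p from 0.223 to 0.715 with an estimated correlation.

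At gene level edgeR called 0 of 15766 genes for the difference immediately after exercise, with 552 at an unadjusted p under 0.05, fewer than the 788 given by chance. DESeq2 called 0 (623 unadjusted), limma-voom 0 (604 unadjusted), and edgeR 2 without an expression filter. The score over 242 responding genes was 1.65 ± 0.160 in control and 1.49 ± 0.508 in blockade subjects, a difference of -0.160 with an exact permutation p of 0.473. Without blockade replicate C it was 0.000211 (exact p = 0.999).

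**Figure D4:**
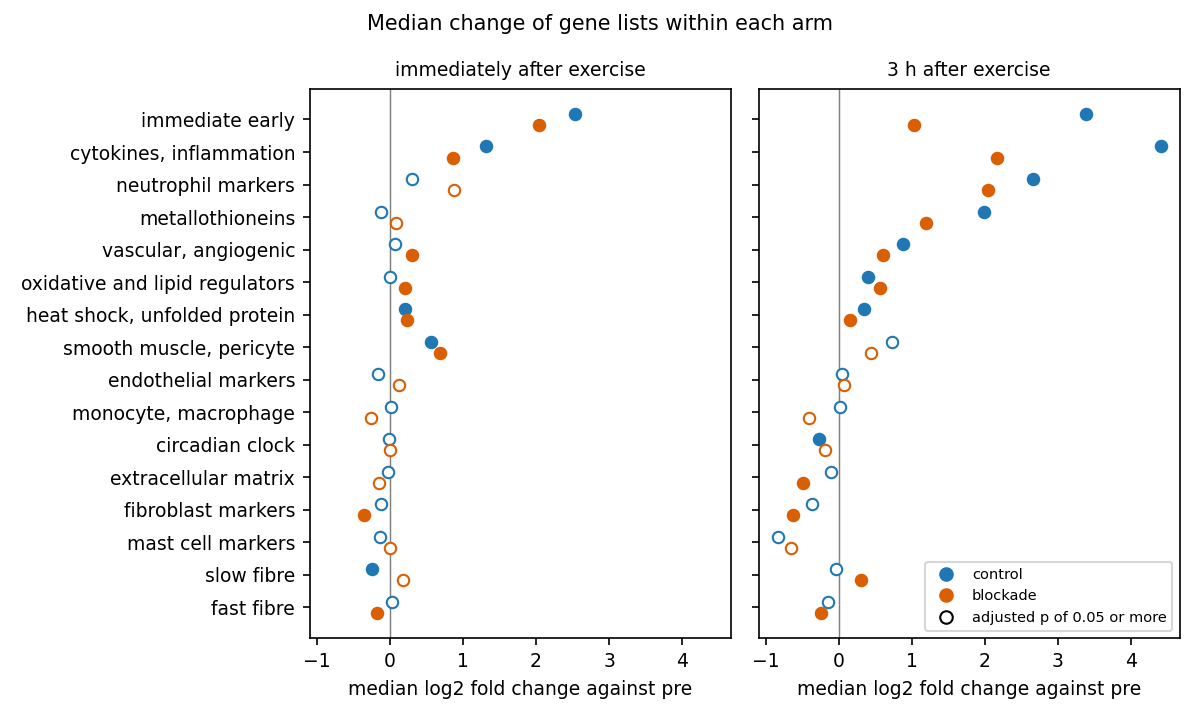
Median log2 change of a selection of the gene lists (x axis) in the comparisons within each arm, with filled points where camera at the preset correlation gave an adjusted p under 0.05. In control muscle at 3 h cytokine and immediate early genes had the largest medians, 4.41 and 3.39, and in blockade muscle their medians were 2.17 and 1.03.

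The last comparison asks whether the arms differed before exercise. Cytosolic ribosomal protein genes had higher estimates in the blockade arm in 23 of 24 members, with a median of 0.20, and mitochondrially encoded genes had lower ones in 13 of 13, with a median of -0.30. Immediate early genes had a median of 0.33, with NR4A1 at 0.65 ± 0.23, CYR61 at 1.05 ± 0.40 and FOS at 1.17 ± 0.47 (adjusted p = 0.781 each). These lists gave camera adjusted p of 1.03e-07, 3.33e-06 and 0.00334, and adjusted p = 0.609 each with an estimated correlation, with 0 members past the threshold. Further lists passed upwards (heat shock, glycolysis, fibroblast and fast fibre) and downwards (clock, red blood cell, vascular, endothelial and slow fibre), with adjusted p from 0.0274 to 0.0499. For all 12 lists the adjusted p was at least 0.609 with an estimated correlation, and 0 of their members passed over all genes (2 of 3 red blood cell genes, lower, adjusted over the list alone). edgeR called 0 of 14180 genes between arms before exercise, with 839 at an unadjusted p under 0.05 where 709 are given by chance, and DESeq2 called 0 (904 unadjusted) and limma-voom 0 (807 unadjusted).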

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

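The tests chosen only after the result was seen were that of the non-muscle cell markers, the direct comparison of the arms at 3 h and the values without the control 3 h library of high mitochondrial share.

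The exercise response at 3 h was smaller in the blockade arm, with a score difference of -0.648 that the permutation of arms put at an exact p of 0.0305. Before exercise the responding genes stood 0.0587 ± 0.0553 (SE) higher in the blockade arm (exact p = 0.348), under 0.5 of the score difference by more than the standard error, which argues against a difference present from the start. Library totals as the scaling gave a difference over all subjects of -0.537 (exact p = 0.0690), against -0.648 with TMM. Without the control subject whose 3 h library stands apart, library totals gave -0.671 ± 0.263 (exact p = 0.0278) and TMM -0.671. That argues against count scaling for the difference among the remaining subjects only. Over all subjects the size of the difference depended on the scaling, so count scaling stays open there. Leukocyte content stays open: with each subject's change in 8 neutrophil markers as a covariate the difference was -0.509 ± 0.258, and with 8 subjects per arm the standard error leaves values under 0.5 of the original within reach. The blockade itself may account for the smaller response, as may other differences between the people of the 2 arms, and the design does not separate these.

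A single control 3 h library stood apart in its mitochondrial share (73.6%), its number of detected genes (17451) and the changes of 5 lists: mitochondrially encoded genes at 3.23, glycolysis at -0.437, ribosomal proteins at -0.607, monocyte and macrophage markers at -1.50 and endothelial markers at -1.26. Read to an equal number of nuclear-encoded reads, 4200851 per library, it showed 17400 genes, inside the range of 17239 to 18359 of the other 7, so the mitochondrial reads by themselves could account for the low number of genes. Across genes its deviation had a Spearman correlation of 0.0812 with exon length, just above the range of -0.122 to 0.0775 in the other 7, so a length bias stays open. Over 9 marker lists of other cell types its median deviation was -1.64, below the range of -0.849 to 1.03 of the others and lower in 9 of 9 lists, from red blood cells at -3.01 to fibroblasts at -0.996, so a piece of muscle with fewer cells of blood, vessels, fat and connective tissue is a candidate explanation. Outside the 9, satellite and Schwann cell markers stood at 0.482 and keratinocyte markers at -0.00175, so not all lists of other cell types were low, and the slow fibre list, which belongs to muscle, was low at -0.938. All 3 of these, the cell content of the piece included, are weighed as technical explanations and may act together. The design gives no biological one for 1 library, so no biological explanation was tested.

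The arms compared directly at 3 h gave 311 genes, 290 of them lower under blockade, where the difference of changes gave 0 by edgeR (1934 unadjusted), 0 by limma-voom and 133 by DESeq2. Before exercise the same genes differed by a median of 0.088 of the 3 h difference (quartiles -0.0693 and 0.257, with the same sign in 197). The genes were picked for a large 3 h difference, which by itself lowers this share. It therefore does not decide whether a difference was present from the start. Over these genes the variance within groups at 3 h was a median of 3.42 times that before exercise (quartiles 2.10 and 6.54, against 1.48 over all genes), so a spread pooled over time points is likely to be too small for them, and the 16 libraries at 3 h alone gave 0 genes by edgeR (1313 unadjusted) and 56 by DESeq2. Of 100 splits of the subjects into arms 3 gave as many genes, the real one included, and the highest of the others gave 659. Few splits reached the count, but the comparison was chosen after the data were seen, so chance is not excluded. An effect of blockade on these genes stays open, as does a difference between the people in the 2 arms.

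Dixon's test for a value far from the rest of its group picked out 17 of 174 groups of 8, where chance gives 8.7, and 7 of the 17 belong to the control 3 h library described above. In 1 control immediate library the mitochondrial share was 39.7%, against 28.1% in the next. Immediately after exercise, single control subjects stood apart with a list change of 0.349 for oxidative regulators, of -0.793 for matrix genes and of -0.167 for glycolysis. Single blockade subjects stood apart at that time with -0.152 for vascular genes, 1.71 for neutrophil markers, -1.62 for adipocyte markers and 0.99 for PPARGC1A. At 3 h the highest change in smooth muscle and pericyte markers in the control arm was 2.01, in a subject other than that of the high mitochondrial share, and the highest change of metallothioneins in the blockade arm was 3.00. The number of gene lists that differed between arms in their change was 7 of 28 immediately after exercise and 13 of 28 at 3 h with the preset correlation, and 0 at both times with an estimated one.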

How the results depend on the processing

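The alternatives chosen only after the data were seen were limma-voom with sample quality weights, a robust prior in edgeR, counts without mitochondrially encoded genes, the values without the control 3 h library of high mitochondrial share and the direct comparison of arms. For changes within arms, 5 kinds of alternative moved the number of genes called by over 1.5 times in at least 1 comparison. Scaling by library totals gave 321 genes for control immediate and 864 for blockade 3 h. It also raised the share of rises from 83.1% to 94.9% for blockade immediate, while it lowered that of control 3 h from 52.1% to 33.1%. Without the replicate block, that is, without pairing by subject, the counts were 284 and 2368 in control and 216 and 641 in blockade muscle, immediately and at 3 h. Fits of only the libraries compared gave 1563 and 2263 in control and 851 immediately after in blockade muscle. Sample quality weights gave 1754 for control immediate, 1145 for blockade immediate and 3403 for blockade 3 h. Leaving out 1 subject gave 1459 to 2818 genes for blockade 3 h, where only the lowest, without blockade replicate G, moved that far. For control immediate, control 3 h and blockade immediate it gave 552 to 897, 3654 to 4931 and 333 to 675 genes, all within 1.5 times. The cause was not tested.

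Before exercise the count of 0 held under every alternative run, and for the difference between arms under most. Without a filter it was 2 immediately and 322 at 3 h, where 39156 genes were tested, and at 3 h it was 133 with DESeq2 and 311 in the direct comparison. Leave-one-out counts at 3 h ran from 0 to 12. The 3 h score difference was -0.537 with library totals (exact p = 0.0690) and -0.279 over falling genes (exact p = 0.0617), and from -0.798 to -0.507 leaving out 1 subject, past 0.05 in 11 of 16. The immediate score ran from -0.231 to 0.000211 and turned sign without blockade replicate C. With an estimated correlation the lists past 0.05 went from 8 to 2, 10 to 0, 10 to 0 and 13 to 1 within arms (control immediate, control 3 h, blockade immediate, blockade 3 h), from 7 to 0 and 13 to 0 between arms, and from 12 to 0 before exercise. Without the control 3 h library of high mitochondrial share the 2 left for control immediate went to 0, and the counts at the preset correlation were 9 for control immediate, 12 for control 3 h, 6 for the difference immediately after and 9 for that at 3 h. Without the replicate block 2 lists passed for blockade immediate with an estimated correlation. Among 874 results for named genes, 55 lost and 3 gained their call with library totals, 7 and 65 without a filter, 0 and 32 with DESeq2, and 7 to 26 and 0 to 13 leaving out 1 subject. Without the replicate block 79 of 763 lost and 6 gained it. Results for differences and before exercise, with 0 calls, had none to lose. Within arms, in the order above, library totals lost 10 of 133, 10 of 128, 5 of 137 and 30 of 127. Without the replicate block the losses were 15, 16, 9 and 39. RPS4X in control muscle at 3 h turned to -0.0103 with library totals (adjusted p = 0.947) and HBA1 turned to -2.545 in the direct comparison at 3 h (adjusted p = 0.046). The planned use of the updated protein-coding counts was not run, because no label ties its columns to libraries. Depth limits low genes most: with 15.9 to 37.7 M reads, IL6 and other genes under 0.1 CPM before exercise had few counts, and their folds depend on the prior count.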

Other observations

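Of the tests here, the direct comparison of the arms at 3 h, the comparison with the authors' lists and the values without the control 3 h library of high mitochondrial share were chosen only after the results were seen.

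Some markers of mast cells, which store histamine, fell by 3 h. In control muscle 4 of 9 markers fell, and 0 rose, over all genes (4 down and 1 up adjusted over the list alone): KIT, the receptor for stem cell factor, by 1.31 ± 0.33, FCER1A by 1.08 ± 0.29, the tryptase gene TPSAB1 by 1.08 ± 0.38 and MS4A2, like FCER1A a part of the IgE receptor, by 1.46 ± 0.52, each in 8 of 8 subjects. The list had a median of -0.84 and a camera adjusted p of 0.0795. In the control 3 h library of high mitochondrial share the list's median deviation was -1.64, and without that library the list adjusted p was 0.0621 and KIT still fell by 1.38 ± 0.34. In blockade muscle 2 of 9 fell, KIT by 1.12 ± 0.33 and FCER1A by 1.17 ± 0.32 (list adjusted p = 0.0741), and the difference between arms was 0.19 ± 0.47 for KIT (adjusted p = 0.927). TPSAB1 has close copies, and reads shared with them were left uncounted.

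Clock genes moved in both arms by 3 h. In control muscle 9 of 18 fell and 3 rose (10 and 3 adjusted over the list alone), with NR1D1, a repressor of the clock, at -1.69 ± 0.19, PER1 at -1.66 ± 0.21, CRY1 at 1.30 ± 0.14 and BHLHE40 at 2.77 ± 0.31 (list adjusted p = 0.0215, and adjusted p = 0.13 with an estimated correlation). In blockade muscle 7 fell and 3 rose (7 and 4 adjusted over the list alone), with NR1D1 at -1.64 ± 0.19 (list adjusted p = 0.0543). The biopsies at 3 h were also taken later in the day than those before exercise, and no series without exercise was measured.

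In blockade muscle at 3 h 2 of 7 adipocyte markers rose, PLIN4, a lipid droplet coat protein that muscle fibres also express, by 0.72 ± 0.18 and LIPE, hormone-sensitive lipase, by 0.80 ± 0.19 (list adjusted p = 0.303). Of 11 monocyte and macrophage markers in the same muscle 1 rose and 1 fell over all genes (1 up and 3 down adjusted over the list alone), namely CD14, a receptor for bacterial lipopolysaccharide, up by 0.90 ± 0.27 and CSF1R, the receptor that maintains macrophages, down by 0.81 ± 0.21. Of the 11, 3 had a positive change, with a median of -0.40 (list adjusted p = 0.166). The satellite and Schwann cell list had 1 of 6 members down (adjusted p = 0.13). Red blood cell genes had 0 of 3 past the threshold in each within-arm comparison, and the keratinocyte list, with 2 measured members and 0 past the threshold (1 up in control muscle immediately after exercise adjusted over the list alone), was too short for the set test.

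List scores per subject compared the arms with an exact permutation test. At 3 h the immediate early list had 3.22 ± 1.52 (SD, n = 8) in control and 1.42 ± 1.40 in blockade subjects (exact p = 0.0308, and 0.224 with Benjamini-Hochberg adjustment over lists), higher than before exercise in 8 of 8 control and 7 of 8 blockade subjects. Without the control subject whose 3 h library had the high mitochondrial share, the exact p was 0.0536. Immediately after exercise the endothelial list had -0.18 ± 0.12 in control and 0.13 ± 0.28 in blockade subjects (exact p = 0.00824, and 0.231 after adjustment), and no list passed after adjustment at either time.

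Swaps of the pre and post libraries within subjects were drawn 100 times from 128, in fits of only the libraries compared. The real order gave the most genes in 1 of 100 each time, the smallest share that 100 splits can give. That argues against chance for the 4 within-arm counts of these fits. They were 1563 against 0 for control immediate, 2263 against 1 for control 3 h, 851 against 637 for blockade immediate and 2033 against 1081 for blockade 3 h, each against the highest of the other splits. The margin was thin for blockade immediate, where the split with 637 had 1 subject swapped. At an unadjusted p under 0.05 that split gave 3070 genes, against 2935 in the real order. For both differences and before exercise edgeR called 0 genes. All 100 splits of the subjects into arms, drawn from 6435, reach such a count whatever the data, so it says nothing about chance. The highest of the others gave 5 immediately, 220 at 3 h and 1 before exercise. DESeq2 called 0, 133 and 0, counts not put through the splits. In edgeR 552, 1934 and 839 genes had an unadjusted p under 0.05. For those 1934 genes at 3 h, 5 of 100 splits gave as many, so chance cannot be excluded, with 2215 in the highest of the others.

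The authors' updated lists hold protein-coding genes with an adjusted p up to 0.1. They list 352 genes for control immediate, 3102 for control 3 h, 267 for blockade immediate and 1037 for blockade 3 h. Of those tested here, 322 of 323, 2725 of 2730, 246 of 246 and 949 of 949 had the same direction, and 314, 2628, 239 and 920 were called here. At 3 h they list 806 genes that differ between the arms at that time point, which is not a difference of changes, 709 of them lower under blockade, of which 687 were tested here. When the arms were compared directly at 3 h, 267 of these were called and 475 had an adjusted p under 0.1. As a difference of changes, which is another contrast, 680 had the same direction, 437 had an unadjusted p under 0.05 and 0 were called. Their lower genes include 22 of the immediate early list, 21 of the cytokine list and 9 neutrophil markers.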
